A study of Drosophila melanogaster with 2 samples.

How the data were processed

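Chromatin from whole adult female flies of a line stably expressing CG7101 fused to GFP was fragmented by sonication and precipitated with an antibody against GFP, per the labels. The labels name 2 biological replicates, which form the 1 group. Per the deposited descriptions, peaks were called for each replicate and for the pooled replicates against a control, and an IDR step on the replicate and pooled lists gave the IDR peaks. The control data set was not analysed here. The aligner, the peak caller and the IDR threshold are not given in the sources used here. Coordinates are those of dm6, per the labels, and are printed counting from 1.

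The deposited lists give each peak's signal, the strength written by the authors' peak caller, whose scale is not stated. They also give the −log10 of the caller's q value as deposited by the authors, which equals its maximum of 4.32 in 100% of the IDR peaks and was therefore not used for ranking. Each of the replicate and pooled lists ends at 30000 peaks, so their weakest peaks depend on that limit (the largest q was 0.297 in replicate 1 and 0.208 in replicate 2). The IDR peaks were the 6486 strongest rows of the pooled list, with signals down to 141.97 against 141.94 for the next pooled peak, so that the IDR list is a threshold on pooled signal. Signal was used only within a list. In the IDR list 106 peaks repeated an interval with another summit, and each summit was kept. Read counts were not analysed here, so depth and its effect on precision are unknown.

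Genes and TSSs came from the Ensembl release 115 annotation, without transposable elements, and sequence from the Release 6 assembly, whose arm lengths were compared with dm6 before use. Only arms 2L, 2R, 3L, 3R, 4 and X were used. Promoters were positions within 500 bp of any annotated TSS. Gene lists, sequence words, their tests and the rule for naming genes were chosen before the data were examined. The count of bound genes by arm, the trends with peak strength, the tests of explanations and the alternatives named as such in the closing section were added afterwards. The rule named the 25 IDR peaks with the highest signal by their nearest TSS, the 4 members with the strongest promoter peak of each list past the threshold (at most 2 for the others), and CG7101, w, y and v. Members of the lists were matched by symbol or, where exactly 1 protein-coding gene carried it, by an older symbol.

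Replicate overlap required 1 bp and was compared with 100 random circular shifts, rank agreement with 100000 random pairings, and promoter share with 1000 draws of random positions. Arm counts were tested by exact binomial tests, gene lists by Fisher's exact tests and words by exact McNemar tests, each adjusted by Benjamini-Hochberg within its family. The difference in median signal used 100000 permutations. A threshold of 0.05 applied throughout. No p-value measures variation between flies, since peaks and genes are not replicates. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

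The procedures were tested on simulated data. With 5% of random positions given TATCGATA, an excess of 5.25% was recovered, no other word was called (0), and the planted word ranked first among 8-base words. Random positions lack the lower GC content of the real summits, so this run does not test for calls that follow base composition. With 2 gene lists planted in 20 simulated runs, 100% were called in the right direction and 0.263% of the other lists were called. Both were long lists planted with large differences, so this does not give the power for shorter lists or smaller differences. Genes were bound independently in these runs. Peaks that count for several neighbouring genes were not simulated, so the rate of false calls in the real lists may be higher. With 50% of peaks kept in place, 49.9% were recovered. Alternatives used each replicate alone, the 3243 strongest IDR peaks, the whole pooled list, other windows, other backgrounds and other definitions of shared peaks. First versions of some tests of explanations were replaced before the values reported here were computed: the GC content of flanks reaches outside most fragments, a count of A/T-only words above their flanks follows from the pattern itself, and lists of genes with high output belonged to the pattern they would have tested.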

Results

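Binding of CG7101 was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole adult female Drosophila melanogaster. The flies carried a transgene for CG7101 with green fluorescent protein (GFP) fused to its C-terminus, and the immunoprecipitation used an antibody against GFP. There was 1 group, with 2 biological replicates, so the data describe where the tagged protein was found and how well the replicates matched, and no comparison between groups was possible. Each replicate had a list of 30000 peaks, as had the pooled replicates. A list of 6486 peaks had passed an irreproducible discovery rate (IDR) threshold, and these are called IDR peaks here. The IDR peaks had a median width of 350 bp and covered 2.03 Mb, or 1.52% of chromosome arms 2L, 2R, 3L, 3R, 4 and X of the dm6 genome. Their signal, the peak strength given by the authors, ran from 142 to 11013 with a median of 245.2. The read depth of the libraries is unknown from the peak lists, and the intervals given below cover counting error over peaks or genes only.

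The strongest peak of the genome, in both replicates, lay at Chro, which encodes the chromosomal protein Chromator. It spanned 3L from 22878500 to 22879467, had a signal of 11013, and its summit at 22878938 lay in the 5' UTR, 46 bp from the nearest transcription start site (TSS). The peak of Gapdh2, a glyceraldehyde 3-phosphate dehydrogenase of glycolysis, came second with a signal of 7594 (X, 15867734 to 15868329), and its intergenic summit lay 167 bp from the TSS. It ranked 2 in replicate 1 and 3 in replicate 2. Peaks at CG14100 (signal 6968), Ugalt (5732, a UDP-galactose transporter), mRpL41 (5528) and mRpS10 (3970, both mitochondrial ribosomal proteins) followed, each with a summit within 500 bp of the TSS. Among the 25 strongest IDR peaks, 17 lay within 500 bp of a TSS, at CG11309, CG1635, CG1888, Fkbp14, CG5611, Tcs5, CG8320, CG18549, CG13390, lncRNA:CR31044 and Lpin besides those named above. The other 8 were named by their nearest TSS, and 7 of them had intronic summits. These included CG11050 (2L, 6612355 to 6612998, signal 6319, 1021 bp from the TSS), CG32772 (signal 5195, 1279 bp), Tlk (signal 4913, 2318 bp), cbt (signal 4478, 1368 bp), Lk6 (signal 4182, 981 bp), norpA (signal 3440, 1379 bp) and lncRNA:CR43287 (signal 3963, 792 bp). The summit at lncRNA:CR44619 lay in a noncoding exon, 539 bp from the nearest TSS. None of the 25 ranked below 31 in replicate 1 or below 39 in replicate 2.

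CG7101 itself, on X from 18830591 to 18832123, had no IDR summit inside the gene and none in the pooled list. The IDR summit nearest to its TSS lay 2061 bp away and had a signal of 233.4. The genes white (w), yellow (y) and vermilion (v), markers widely used in fly transgenesis, had no IDR summit inside the gene either. Their TSSs lay 9013, 18225 and 3327 bp from the nearest IDR summit. In the longer pooled list, w held 4 summits, and y and v held 0.

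Replicates 1 and 2 shared most of their peaks. Of the 30000 peaks of replicate 1, 76.8% (95% Clopper-Pearson interval 76.3 to 77.2) overlapped a peak of replicate 2 by at least 1 bp, and 73.5% (73.0 to 74.0) of the peaks of replicate 2 overlapped one of replicate 1. After random shifts along the arms the shares averaged 15.1% and 14.6% (one-sided permutation p = 0.0099 for each, the smallest that 100 shifts can give). Among the 6486 strongest peaks of each replicate, 83.4% of those of replicate 1 overlapped one of replicate 2. Across 19704 shared peaks, ranks in the lists correlated with a Spearman rho of 0.783 and a Pearson r of 0.721 (permutation p = 1e-05 for each, two-sided, the smallest that 100000 pairings can give). Peaks are not independent replicates. Of the IDR peaks, 6463 overlapped a peak in both replicates and 23 in 1 replicate. Since the IDR list was made from these same replicates, this overlap is not separate evidence of their agreement.

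**Figure D1:**
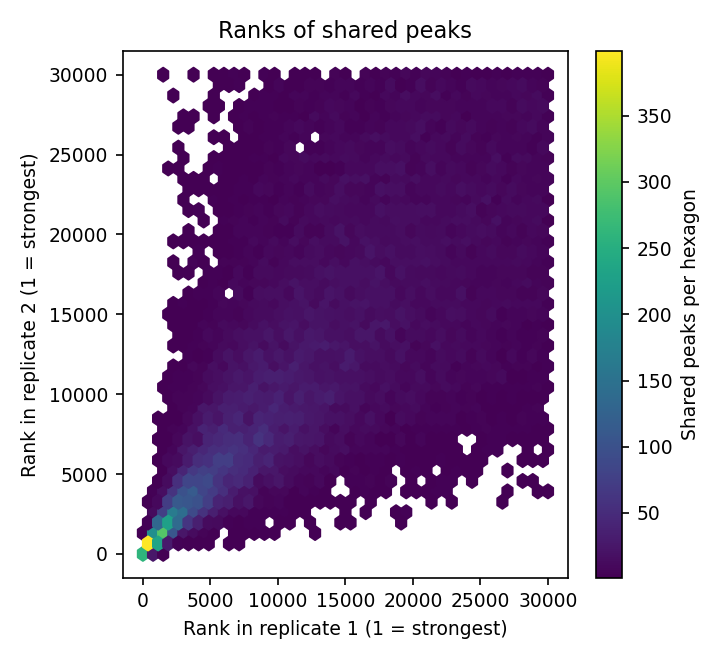
Ranks of peaks shared by the replicates, with the rank in replicate 1 on the x axis and in replicate 2 on the y axis (1 = strongest). Colour gives the number of shared peaks per hexagon, and the 19704 shared peaks (Spearman rho 0.783) lie close to the diagonal at strong ranks and spread widely at weak ones.

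Most IDR summits lay at promoters. Of 6486 summits, 4076 (62.8%, 95% Clopper-Pearson interval 61.7 to 64.0) fell within 500 bp of an annotated TSS, against a mean of 13.5% for random positions on the same arms, a 4.64-fold excess (one-sided permutation p = 0.000999, the smallest that 1000 draws can give). Of the promoter summits, 78.4% (77.1 to 79.6) lay upstream of the nearest TSS, at a median of -73 bp with quartiles of -155 and -10 bp. Outside promoters, introns held 28.2% of all summits (39.6% of random positions), intergenic sequence 6.12% (26.9%), 3' UTRs 0.987% (4.33%) and coding exons 0.185% (13.9%). Annotated transposable elements held 9 summits, or 0.139% (0.0635 to 0.263), against 5.77% of random positions. How reads shared between repeated copies were treated is not given in the sources used here. Rare binding in these elements therefore cannot be told from missing reads. These location classes were compared by their values and were not tested separately. In the whole pooled list of 30000 peaks the promoter share was 39.6%, a 2.92-fold excess. Against random positions within 10 kb of a summit, of which 24.0% lay at promoters, the excess of the IDR summits was 2.62-fold, and with promoter windows of 250 and 1000 bp it was 7.18-fold and 3.09-fold.

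**Figure D2:**
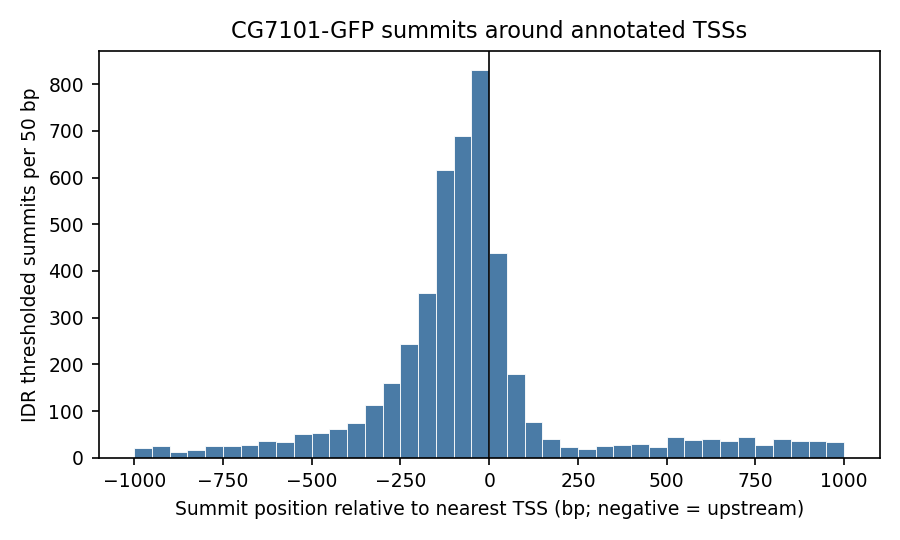
Number of IDR summits per 50 bp (y axis) by position relative to the nearest annotated TSS in bp (x axis, negative values upstream). The highest bar, from -50 to 0 bp, holds 830 summits.

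Peaks at promoters were stronger than other IDR peaks. The median signal was 255.2 over 4076 promoter peaks and 230.4 over 2410 other peaks, a difference of 24.8 (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give). The difference was 43.2 in the whole pooled list, where the medians were 92.4 and 49.1.

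The X chromosome carried more IDR peaks than its length predicts and chromosome 4 fewer. X held 1349 peaks, 57.3 per Mb (95% exact Poisson interval 54.3 to 60.4) and 1.18 times the number expected from arm length (two-sided exact binomial test, Benjamini-Hochberg adjusted p = 1.84e-10 over 6 arms). Chromosome 4 held 32 peaks, 23.7 per Mb (16.2 to 33.5) and 0.490 times the expected number (adjusted exact p = 2.05e-05), and 0.245 times with the 3243 strongest IDR peaks (adjusted p = 2.34e-06). Expected numbers use full arm lengths, including sequence whose reads could belong to several places. Arm 3L lay at 0.931 times (adjusted exact p = 0.00831), and at 0.986 times in the whole pooled list (adjusted p = 0.314). Arms 2L (0.993), 2R (0.994) and 3R (0.957) did not pass the threshold (adjusted exact p = 0.837, 0.837 and 0.0823), though 3R did in the whole pooled list (0.962 times, adjusted p = 0.000358) and without replicate 1 (adjusted p = 0.0349). On X, promoter peaks numbered 31.9 per Mb, within the range of 28.3 to 33.3 on arms 2L, 2R, 3L and 3R, whereas other peaks numbered 25.4 per Mb against 14.9 to 17.6 on those arms. Counted by gene, 35.5% of 2196 protein-coding genes on X were bound, against 32.9% elsewhere (Fisher's exact test, two-sided, adjusted p = 0.0469 over 6 arms, chosen after the data were seen). On 2L 30.6% of 2657 genes were bound, against 33.9% elsewhere (adjusted exact p = 0.00753), and arms 2R, 3L, 3R and 4 did not pass. These counts kept the 111 unbound histone genes whose start-site sequence recurs, and the arms were not compared without them. A lower share on an arm that carries many of them cannot be told from missing reads here.

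Genes of protein synthesis were bound often. A gene counted as bound when an IDR summit lay within 500 bp of one of its TSSs, which held for 4641 of 13945 protein-coding genes (33.3%). A peak near the start sites of several genes counted for each of them. Of 93 cytosolic ribosomal protein genes 82 were bound (88.2%, interval 79.8 to 93.9, against 32.9% of other genes, adjusted exact p = 3.47e-27), led by RpS27 (signal 2258), RpL34b (1739), RpL7 (1637) and RpL14 (1628). Of 73 mitochondrial ribosomal protein genes 51 were bound (69.9%, adjusted exact p = 1.1e-09), led by mRpL41 (5528), mRpS10 (3970), mRpS23 (3294) and mRpL23 (2735). Translation initiation factors (24 of 44 bound, 54.5%, adjusted exact p = 0.00608) included eIF4EHP (3285), eIF6 (3240), eIF1 (1188, a peak that also counted for RpL28) and eIF3h (634). Aminoacyl-tRNA synthetases (18 of 33, 54.5%, adjusted exact p = 0.0221) included SerRS (1158), GluProRS (676), IleRS (616) and ThrRS (482). All p-values of gene lists are from two-sided Fisher's exact tests, adjusted by Benjamini-Hochberg over 21 lists, of which 7 were bound more often than other genes, 8 less often and 6 did not pass. With genes that have no other gene's TSS within 1 kb, 4 lists remained past the threshold, and among the lists of this paragraph it was the cytosolic ribosomal proteins alone (17 of 21 genes, adjusted exact p = 1.21e-08). The odds ratio there was 2.34 for initiation factors (7 of 20 genes bound, 2.41 with all genes), 1.92 for mitochondrial ribosomal proteins (4 of 13, 4.69 with all genes) and 0.617 for synthetases (1 of 8, 2.41 with all genes). Without replicate 2 the initiation factor and synthetase calls were lost (adjusted exact p = 0.0688 and 0.0551), at odds ratios of 1.86 and 2.16. Initiation factors did not pass with the 3243 strongest IDR peaks either (7.53 percentage points above other genes, 21.3 with all IDR peaks, adjusted exact p = 0.295), in the whole pooled list (odds ratio 2.30, adjusted p = 0.0524) or among genes with 1 TSS position (odds ratio 1.67, adjusted p = 0.289). Synthetases did not with a 1000 bp window (odds ratio 2.07, adjusted exact p = 0.0679).

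Chromatin and cell cycle genes were bound often as well. Of 68 genes for chromatin and insulator proteins 46 were bound (67.6%, interval 55.2 to 78.5, adjusted exact p = 2.6e-08), led by Chro (11013), the Polycomb gene ph-p (2994), brm (2220), the ATPase of the Brahma remodelling complex, and the insulator gene Cp190 (2065). Cell cycle and DNA replication genes (31 of 60, 51.7%, adjusted exact p = 0.00608) included Cdc16 (911), dpa (704), CycE (673) and dup (649). Of 32 proteasome genes 17 were bound (53.1%, adjusted exact p = 0.0323), with Rpn3 (547), Rpn5 (507), Rpt5 (495) and Rpn2 (404) strongest. Chromatin genes kept their call among genes without a neighbouring TSS within 1 kb (10 of 18, adjusted exact p = 0.00279). The cell cycle and proteasome calls were lost there with few genes left, at odds ratios of 2.02 (7 of 22 bound, 2.15 with all genes, adjusted exact p = 0.314) and 2.89 (4 of 10, 2.28 with all genes, adjusted p = 0.234). Cell cycle genes also did not pass with a 250 bp window (9.78 percentage points above other genes, 18.5 with 500 bp, adjusted exact p = 0.141), proteasome genes did not with a 1000 bp window (adjusted p = 0.0864) or among genes with 1 TSS position (adjusted p = 0.0904), and neither list did with the 3243 strongest IDR peaks (adjusted p = 0.0859 for each).

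Lists for chemoreceptors, cuticle, gut proteases, chorion, patterning, the nervous system and cytochrome P450 were bound less often than other genes. Of 231 genes for chemoreceptors and odorant-binding proteins 2 were bound (0.866%, adjusted exact p = 2.4e-36), Ir60e (signal 390.0) and Gr63a (177.6). Of 117 cuticle protein genes 1 was bound, Lcp9 (201.2, adjusted exact p = 1.5e-18). Of 35 gut protease and amylase or maltase genes 1 was bound, Mal-A5 (1371, adjusted exact p = 5.14e-05). None of 18 chorion and vitelline membrane genes was bound (0%, upper limit of the exact interval 18.5%, adjusted exact p = 0.00192). Homeotic and patterning genes (8 of 60 bound, 13.3%, adjusted exact p = 0.00192) included cnc (896), fkh (817), tin (708) and hry (336). Nervous system genes (7 of 51, 13.7%, adjusted exact p = 0.00531) included elav (1923), NaCP60E (1008), sei (593) and RIC-3 (338). Cytochrome P450 genes (16 of 85, 18.8%, adjusted exact p = 0.00608), a list that its naming pattern extends to the cyclophilins Cyp1 and Cyp40, included Cyp6u1 (1313), Cyp28d1 (474), Cyp6w1 (418) and Cyp6t1 (331). In the whole pooled list the P450 and nervous system differences turned positive and did not pass (adjusted exact p = 0.552 and 0.734), and the gut, chorion and homeotic calls were lost (adjusted p = 0.622, 0.731 and 0.622). Among genes without another gene's TSS within 1 kb, chemoreceptors (0 of 163 bound, adjusted exact p = 4.46e-14) and cuticle proteins (0 of 96, adjusted p = 2e-08) passed, whereas P450 genes (-1.88 percentage points from other genes, adjusted p = 0.965) and homeotic genes (-6.06 points, adjusted p = 0.528) did not. Nervous system (1 of 33 bound, odds ratio 0.134 against 0.318 with all genes, adjusted exact p = 0.0568), chorion (0 of 13, adjusted p = 0.306) and gut genes (1 of 19, odds ratio 0.240 against 0.0588, adjusted p = 0.408) did not pass there either but were still rarely bound. With the 3243 strongest IDR peaks the P450, chorion and nervous system calls were lost (adjusted exact p = 0.164, 0.0715 and 0.111), P450 genes did not pass among genes with 1 TSS position (adjusted p = 0.163), and nervous system genes did not with a 1000 bp window (adjusted p = 0.081).

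Histone genes formed the other rarely bound list, with 4 of 115 genes bound (3.48%, adjusted exact p = 2.07e-14). The bound members were His2Av (442), His3.3B (264.3), His4r (189.7) and His3.3A (187.1), and sequence near the start sites of each of the other 111 genes recurs, in part or whole, elsewhere on the arms. Among genes without another gene's TSS within 1 kb, 1 of 24 histone genes was bound (4.17% against 18.8%) and the list did not pass (adjusted exact p = 0.234). The lists that did not pass were oxidative phosphorylation (37 of 84 bound, 44.0%, adjusted exact p = 0.0624, with ND-ASHI at 1076 and ND-42 at 789), innate immunity (21 of 48, adjusted p = 0.157, with imd at 1316 and cact at 1072), heat shock (10 of 26, adjusted p = 0.711, with Hsp83 at 2143 and Hsp27 at 1854), germline and oogenesis (20 of 56, adjusted p = 0.711, with papi at 2793 and orb at 911, the same peak as for Cdc16), muscle (8 of 34, adjusted p = 0.322, with Msp300 at 1431 and mys at 485) and yolk proteins (1 of 3, adjusted p = 1, with Yp3 at 508). Oxidative phosphorylation genes did pass, as bound more often, with replicate 2 alone (adjusted exact p = 0.0139), with a 250 bp window (adjusted p = 0.029) and in the whole pooled list (adjusted p = 0.00626), and muscle genes, as bound less often, with a 250 bp window (adjusted p = 0.0455). Against genes of any biotype, tRNA genes (33 of 290 bound, 11.4% against 27.9%, adjusted exact p = 2.77e-11) and snoRNA genes (27 of 269, adjusted p = 4.87e-12) were bound less often, and snRNA genes (7 of 32, adjusted p = 0.556) did not differ past the threshold. Whether sequence near these RNA genes recurs elsewhere on the arms was not examined.

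**Figure D3:**
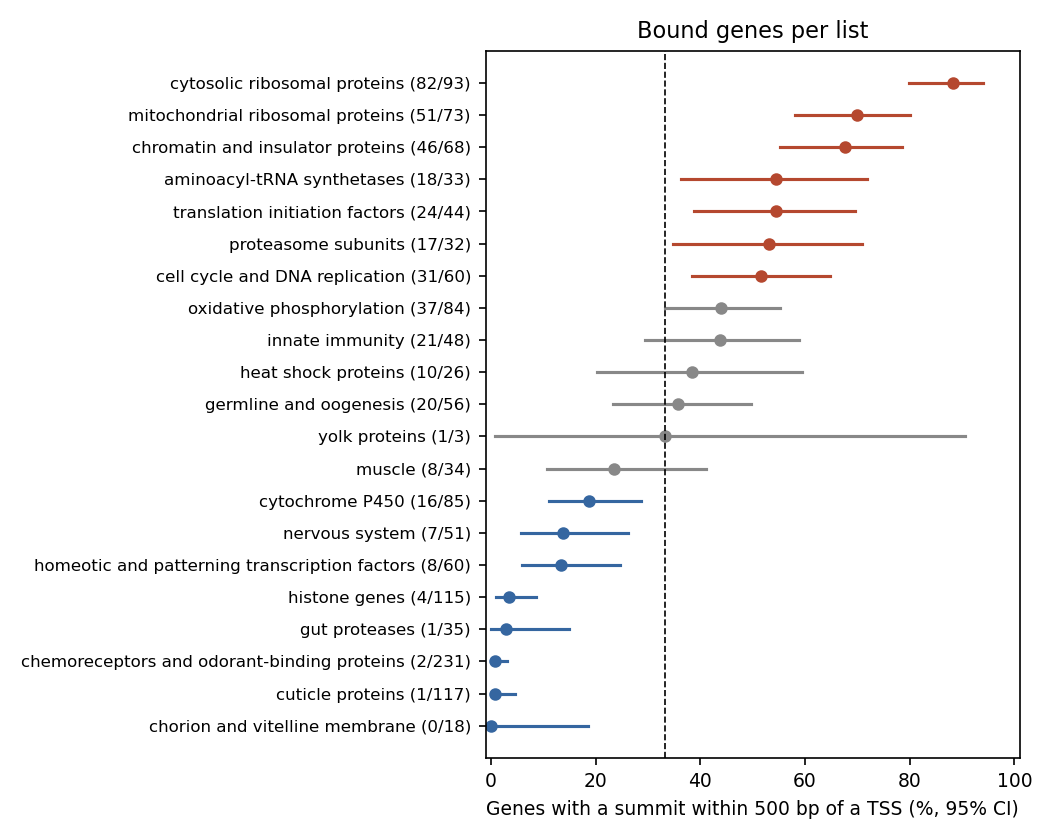
Percentage of the genes of each list with an IDR summit within 500 bp of a TSS (x axis), with 95% Clopper-Pearson intervals as lines and bound and total members beside each list name. Red lists were bound more often and blue lists less often than other genes, grey lists did not pass, and the dashed line marks the 33.3% of all protein-coding genes.

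TATCGATA and Motifs 1, 6 and 7 were concentrated at the summits. The DNA replication-related element TATCGATA occurred within 100 bp of 369 summits (5.69%, interval 5.14 to 6.28), against a mean of 0.617% in windows 500 bp to either side (adjusted exact p = 2.57e-67). Motif 1, GGTCACACT, occurred at 2.93% of summits against 0.370% (adjusted exact p = 3.29e-28), Motif 6 at 1.02% against 0.185% (adjusted p = 8.26e-08), and Motif 7 at 10.3% against 3.38% (adjusted p = 3.9e-60). Against random windows of the same location class these 4 words also passed, with smaller excesses. TATCGATA was at 1.34% of those windows (4.24-fold), Motif 1 at 0.678% (4.32-fold, 7.92-fold against the flanks), Motif 6 at 0.308% (3.30-fold) and Motif 7 at 4.73% (2.17-fold). The promoter class reaches 500 bp from a TSS, whereas promoter summits lay at a median of -73 bp. Neither control matched the distance to the TSS. Words that lie close to start sites in general therefore cannot be told from words particular to these peaks. Among the 811 strongest IDR peaks Motif 1 (0.863% against 0.493%, 1.75-fold) and Motif 6 (0.986% against 0.123%, adjusted exact p = 0.160) did not pass, nor did Motif 6 among the 810 weakest (1.11% against 0.123%, adjusted p = 0.216). The excess of Motif 6 was no smaller in these sets, at 8-fold and 9-fold against 5.5-fold with all IDR peaks, but these folds rest on 8 and 9 summits. GATA words (38.8% against 30.4%, adjusted exact p = 9.03e-25), the TATA box (4.35% against 2.49%, adjusted p = 1.45e-08), A tracts (13.4% against 11.7%, adjusted p = 0.0156) and the Su(Hw) core (0.555% against 0.285%, adjusted p = 0.0156) were also more frequent. Words for E2F (8.25% against 10.6%, adjusted exact p = 4.45e-05), the pause button (9.07% against 11.5%, adjusted p = 0.000121), CA repeats (4.90% against 6.77%, adjusted p = 6.98e-05), Zelda (0.817% against 1.34%, adjusted p = 0.00606) and the downstream promoter element (3.04% against 3.79%, adjusted p = 0.0274) were less frequent. The tests were two-sided exact McNemar tests against the window on the side of higher coordinates, whatever the strand of the gene. They were adjusted by Benjamini-Hochberg over 22 words, of which 8 were more and 5 less frequent at summits. Among the words that did not pass were the initiator (18.2% against 17.0%, adjusted exact p = 0.0743), TCT (a difference of -0.802 percentage points, adjusted p = 0.600) and GAGA (5.20% against 4.58%, adjusted p = 0.095). GC content averaged 37.1% within 100 bp of the summits and 43.5% in the windows beside them. The word tests do not correct for this difference. A higher frequency of AT-rich words (GATA, TATA box, A tracts) therefore cannot be told from base composition here. The same holds for the lower frequency of GC-rich words (E2F, pause button, downstream promoter element). CA repeats became more frequent at summits than in random windows of the same location class (4.90% against 3.82%, adjusted exact p = 0.00658) and than in the flanks of the whole pooled list (adjusted p = 0.0129), and pause button words in the pooled list likewise (adjusted p = 0.0123). Against the same random windows the calls for Su(Hw), Zelda and E2F were lost (adjusted exact p = 0.0502, 0.154 and 0.0734). The fold hardly moved for Su(Hw) (1.89, 1.95 against the flanks) and came closer to equal frequency for Zelda (0.736, from 0.609) and E2F (0.892, from 0.780). GAGA was more frequent at summits than in these windows (5.20% against 3.05%, adjusted exact p = 3.98e-09), as it was in the pooled list (4.97% against 3.44%, adjusted p = 8.9e-22). The downstream promoter element call was lost with either replicate alone (adjusted exact p = 0.241 without replicate 1 and 0.0684 without replicate 2), and the Su(Hw) and Zelda calls were lost without replicate 2 (adjusted p = 0.0915 and 0.121). A tracts did not pass with 50 bp windows (adjusted exact p = 0.126) or in the whole pooled list (0.385 percentage points, adjusted p = 0.258). With 50 bp windows the downstream promoter element, Su(Hw) and Zelda did not pass either (adjusted exact p = 0.192, 0.222 and 0.138), and the initiator was more frequent at summits without replicate 1 and without replicate 2 (adjusted p = 0.047 and 0.00746) and in the pooled list (adjusted p = 2.99e-11). Su(Hw) also did not pass with the 3243 strongest IDR peaks (0.493% against 0.262%, adjusted exact p = 0.316). Other words passed in some settings, namely the E-box as more frequent (10.8% against 9.36% in the random windows, adjusted exact p = 0.0158, and adjusted p = 0.0462 in the pooled list), and as less frequent G tracts (adjusted p = 0.00486 with the 3243 strongest peaks, 0.0288 without replicate 1), TCT (adjusted p = 0.0204 in the pooled list) and Grainyhead (adjusted p = 0.0145 without replicate 1). GAGA passed without replicate 1 as well (adjusted exact p = 0.0174), and CTCF was less frequent at the 811 strongest summits (5.06% against 7.27%, adjusted p = 0.042).

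At the 2410 summits more than 500 bp from a TSS, 4 of the 22 words passed. GATA words were more frequent (45.1% against 33.6%, adjusted exact p = 1.97e-14), and words for E2F (7.01% against 10.2%, adjusted p = 0.000446), the pause button (6.80% against 10.5%, adjusted p = 0.000446) and the downstream promoter element (2.28% against 3.69%, adjusted p = 0.00295) were less frequent. These comparisons did not correct for base composition either. TATCGATA occurred at 0.705% of summits against 0.415% (adjusted exact p = 0.551). Motif 1 (0.0415% against 0.311%, adjusted exact p = 0.0788), Motif 6 (0.166% against 0.145%) and Motif 7 (3.65% against 3.17%, adjusted p = 0.174) did not pass either. Of the 20 leading 8-base words found on arms 2L, 2R and X, all 20 were again more frequent at summits than beside them on 3L, 3R and 4. They are not 20 separate motifs. Of them, 7 hold only A and T, whose frequency follows the lower GC content of summits, and several others overlap TATCGATA or GGTCACACT. TATCGATA led (5.06% against 0.538% on the held-out arms, adjusted exact p = 4.78e-23), followed by ATCGATAG (4.99% against 0.610%), and GGTCACAC (3.91% against 0.592%) and CAACACTG (4.12% against 0.574%) were also among them. Away from promoters the leading word was CACTGTGC (2.65% against 0.539% on the held-out arms, adjusted exact p = 0.0033), and CCACTGTA (3.04% against 0.490%, adjusted p = 3.47e-05) was another of these 20, all of which passed on the held-out arms. In this set too 7 words hold only A and T, and several others share CACTGT.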

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

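The alternatives that use the strongest and weakest 811 and 810 peaks, genes with 1 TSS position and histone genes without recurring copies were chosen after seeing the data. Replicate overlap, rank agreement, promoter share, the excess on X and the signal difference at promoters kept their direction and side of the threshold under every alternative run. The share of replicate 1 peaks overlapping replicate 2 ran from 53.5% (summits within 100 bp) to 83.4%, the promoter share from 39.6% (whole pooled list) to 72.9% (1000 bp window), and X from 1.09 to 1.19 times the expected peaks. Of 15 gene lists past the threshold, 9 passed with the 3243 strongest IDR peaks, 4 with genes that have no other gene's TSS within 1 kb, and 9 in the whole pooled list together with 1 other list. The 1 other list was oxidative phosphorylation. Of 13 words past the threshold, 9 passed in the 811 strongest peaks (without Motifs 1 and 6, DPE and Su(Hw)), 4 at peaks away from promoters and 3 in the 810 weakest peaks. In the 811 strongest peaks the difference was smaller for Motif 1 (1.75-fold at 7 summits, 7.92-fold with all IDR peaks) and Su(Hw) (1.33-fold at 2 summits, 1.95-fold). It was no smaller for Motif 6 (8-fold at 8 summits, 5.5-fold) and DPE (0.508-fold at 16 summits, 0.802-fold). With so few summits, whether the excess of Su(Hw) shrank or that of Motif 6 held cannot be told. Why these calls were lost was not tested. Using 1 replicate alone gave 13 to 16 lists, 11 to 16 words and 3 to 4 arms. No paired analysis was possible because there was 1 group.

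Some differences changed sign, mostly of lists, words and arms that had not passed, and for these the cause was not tested. Percentage points are given for lists (list minus other genes) and words (summit minus control). In the whole pooled list, arms 2L and 2R lay at 1.01 and 1.00 times the expected peaks, heat shock genes at -9.05, P450 genes at 5.39, nervous system genes at 3.81, DPE at 0.163, AP-1 at 0.0483, pause button at 0.465, CA repeat at 0.58 and G tract at 0.162. In the 3243 strongest IDR peaks, arm 2L lay at 1.01, E-box at -1.02, GAGA at -0.355, initiator at -0.37, TCT at 0.432, CTCF at -1.06 and ETS at 0.17. With each replicate left out in turn, arm 2R ranged from 0.983 to 1.00, CTCF from -0.185 to 0.262 and ETS from -0.0308 to 0.00771. Yolk genes lay at -28.6 with a 250 bp window and -3.42 with 1000 bp, synthetases at -6.29 among genes without a neighbouring TSS, and heat shock and immunity genes at -15.1 and -1.14 among genes with 1 TSS position. Histone genes lay at 66.5 without recurring copies, a set of 4 genes. With 50 bp windows, GAGA lay at -0.378, AP-1 at 0.0848 and ETS at 0.0925. Against matched random windows, TCT lay at 0.586, AP-1 at 0.185, ETS at 0.0154, CA repeat at 1.08 and G tract at 0.0617. Away from promoters, Motif 1 lay at -0.27, E-box at -1.85, GAGA at -0.996 and initiator at -0.851. In the 811 strongest peaks, E-box lay at -2.71, GAGA at -0.925, initiator at -2.4, TCT at 0.801, CTCF at -2.22 (past the threshold there, adjusted exact p = 0.042), AP-1 at 0.123 and ETS at 0.555, and in the 810 weakest, Grainyhead at 0.185, ETS at 0.0617 and CA repeat at 0.864. Read depth is unknown, so its limits could not be assessed.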

Other observations

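The trends with peak strength, the histone test, the split of the housekeeping lists, the other fragment lengths and the shuffles of weak summits and flanks below were chosen after the data were seen. The shuffles of the strongest summits, the partial correlation and the 2 tests on the 6 housekeeping lists together were written down before their values were computed but after the patterns they address. Since there was 1 group, no biological explanation was tested.

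Peaks at different strengths sat on different sequence. Among the 811 strongest IDR peaks, 70.5% lay at promoters (95% Clopper-Pearson interval 67.3 to 73.7), against 56.9% (53.4 to 60.4) of the 810 weakest. Motif 1 went the other way, with GGTCACACT at 0.863% (0.348 to 1.77) of the strongest (0.493% in their flanks) and 4.07% (2.82 to 5.67) of the weakest summits (Spearman rho with signal -0.0576, permutation p = 1e-05, adjusted p = 2.2e-05 over 22 trends). For TATCGATA no trend over all IDR peaks passed (rho = -0.0202, adjusted p = 0.132), but among promoter peaks it was less frequent at stronger peaks (rho = -0.0447, adjusted permutation p = 0.00676). CCACTGTA occurred at 4.69% (3.34 to 6.37) of the 811 strongest summits and at 1.11% to 2.10% in the 7 weaker groups of about that size. These correlations are across peaks, which are not independent replicates.

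Stronger peaks sat on more AT-rich summits. Mean GC content within 100 bp was 33.3% (SE 0.256 across peaks) in the 811 strongest and 39.4% (SE 0.283) in the 810 weakest, with rho = -0.249 over all IDR peaks, while 500 bp beside the summits it went slightly the other way (rho = 0.0917, adjusted p = 2.2e-05 for both). Given GC content within 250 bp, the partial rho was -0.244 (95% bootstrap interval -0.269 to -0.222), and over centred fragments of 300 to 800 bp it ran from -0.214 to -0.267, but the labels give library sizes from 200 bp, as wide as the summit window, where the correlation cannot tell a GC bias of the libraries from the pattern, so this bias stays open. Shuffles that keep dinucleotides cannot settle whether 1 AT-only word or base composition goes with strength: at the 1000 strongest summits AAATATAT exceeded its shuffled mean by 9.05 percentage points, and by 7.07 when shuffled within blocks of 40 bases, more than any A/T-only word in 100 shuffles (4.13 and 3.39). A repeat of the shuffles put AAATATAT at 2.59 times its shuffled mean there (95% bootstrap interval 2.24 to 2.98). It lay at 2.65 times (2.09 to 3.16) at the 1000 weakest summits and at 3.35 times (2.53 to 4.24) 500 bp to 1 side of the strongest. Within blocks the values were 1.90, 1.93 and 2.44 times, so this excess was not particular to strong summits and both explanations stay open.

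The 111 histone genes without a peak may be missing for a technical reason. Of the 50-base tiles within 100 bp of their start sites, 98.4% recur on the chromosome arms, so reads from them could belong to several copies. The 4 histone genes with unique tiles, His2Av, His3.3A, His3.3B and His4r, were all bound, which turned the difference from other genes from -30.1 to 66.5 percentage points (adjusted p = 0.0204, Fisher's exact test). They are the same 4 genes already known to be bound when this split was chosen, so the p-value is not separate support. Whether they differ from the 111 in more than copy number was not examined. Reads shared between gene copies therefore remain a possible reason, and how such reads were treated upstream is not given in the sources used here.

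Housekeeping genes were bound more often than other genes also in 2 subsets with simpler start sites. The lists of cytosolic and mitochondrial ribosomal proteins, proteasome, oxidative phosphorylation, initiation factors and synthetases together had 229 of 359 genes bound (63.8% against 32.5% of others). Among genes with 1 annotated TSS position the share was 57.1% against 26.1% (Fisher's exact p = 2.68e-23), which argues against the number of start sites as the whole cause for the lists together. On their own, both ribosomal protein lists and synthetases passed there. Proteasome (10 of 22, adjusted exact p = 0.0904), initiation factor (11 of 29, adjusted p = 0.289) and oxidative phosphorylation genes (17 of 50, adjusted p = 0.315) did not, and for these the number of start sites stays open. Among genes without another gene's TSS within 1 kb the share of the lists together was 40% against 18.5% (p = 8.02e-07, two-sided Fisher's exact tests), and for cytosolic ribosomal proteins alone 81.0% (17 of 21 genes), which argues against neighbouring start sites as the whole cause there. For the other 5 lists together it was 29.1% (23 of 79, interval 19.4 to 40.4, unadjusted exact p = 0.0199), with an odds ratio of 1.81 against 2.57 among all genes. This rests on 1 test of a split chosen after the data were seen, and synthetases went the other way (1 of 8, odds ratio 0.617). For these 5 lists neighbouring start sites therefore stay open as a cause, in part or whole. How widely each gene is transcribed stays open for all the lists.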
